A study of Mus musculus with 84 samples.

How the data were processed

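RNA of 84 libraries of sorted mouse progenitors was measured by sequencing. Per the labels, RNA was prepared with a Qiagen RNeasy micro plus kit and libraries with a Clontech SMARTer kit. The deposited values are raw counts of reads per Ensembl gene, which the authors made with STAR (3.0.4 in their notes), Subread (version not given) and featureCounts 1.4.5. The genome build, annotation and strand setting are not given in the sources used here. The table held 41391 genes as lines, 41388 of them mouse genes and 3 for the transgene: human KMT2A, human MLLT1 and the fusion, which equalled the sum of both human genes in all 84 libraries. Symbols and positions came from GENCODE vM21 on GRCm38, with a symbol for 40340 mouse identifiers; the other 1048 took 0.155% of counts. There were 13237 mouse genes at 0 in every library. Totals ran from 7.62 to 29.47 M counts per library, with a median of 14.75 M. Floors for genes at 0 are 3 counts over the group, and floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Among 120 pairs of libraries within groups none was a duplicate of another (chi-square per degree of freedom from 8.51 to 148.74).

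Libraries were grouped by age, population and genotype from their labels, in 3 sets by their identifiers: 47 libraries at P0 and 10 weeks, 16 at 6 and 12 months, and 21 of the MLL-ENL (x2) series with its own controls. Each set was fitted on its own with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test after TMM scaling and filterByExpr, with 1 mean per group and Benjamini-Hochberg FDR 0.05. The fits held 14899, 13059 and 14260 genes with a common biological coefficient of variation of 0.297, 0.224 and 0.268. Differences between effects were tested as contrasts of 4 groups, and those across sets in 1 fit of the compared groups of both sets. Gene lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one, adjusted over the 22 lists within each of 28 comparisons. The lists were MLL fusion targets, stem and multipotent progenitor, neutrophil granule, monocyte and dendritic, MHC class II, lymphoid priming, T and NK cell, erythroid, megakaryocyte, mast cell and basophil, fetal and neonatal, type I interferon response, mitosis, DNA replication, ribosome biogenesis, oxidative phosphorylation, p53 response, immediate early, inflammatory NF-kB, hepatocyte, stroma and endothelium, and sorting antigens. Transgene levels were compared by 2-sided exact permutation tests, adjusted over 13 comparisons. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used beside R.

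Groups, comparisons, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. By that rule Kmt2a and Mllt1 were named throughout, and in each comparison the 10 genes that rose and the 10 that fell most among those past FDR 0.05, with a mean of at least 1 on the log2 CPM scale (prior count 2), no overlap between the groups where 2 groups were compared, and no predicted gene model. Of each list up to 4 members past FDR with the smallest p were named, or 2 members with their values where none passed. Hoxa genes, Meis1 and sex-linked genes were named where of use. Genes outside the rule are said to be chosen after their values were seen. A list of type 1 conventional dendritic cell genes and the fits without the libraries labelled 73 were chosen after seeing the data.

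Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, fits of the compared groups alone or of all 84 libraries, the replicate or animal number as a block, the 10 week controls of both sets pooled, the estimated correlation, FDR 0.10 for overlaps, and leaving out each library in turn. A change of sign counts as a reversal only where the main or the alternative value was called. RLE against TMM shifted all log2 fold changes of a comparison by at most 0.05. By expression, P0 control and MLL-ENL libraries matched best with their own replicate number in 3 of 3 pairs of pGM and 4 of 4 of GMP, against 2 of 4 of HPC. Blocked counts therefore stand beside the P0 pGM and GMP results. On data simulated with the gene-wise spread of the whole fit of 47 libraries, edgeR tested P0 HPC. It recovered 39.8% of genes changed 2-fold and 77.1% of genes changed 4-fold, and called 5 unchanged genes (DESeq2 21). With the spread of the 21 libraries of the MLL-ENL (x2) set, tested in HPC, it recovered 47.4% and 80.6% (6 unchanged called, DESeq2 19). With that of the 16 libraries at 6 and 12 months, tested at 12 months, it recovered 59% and 95% (6 unchanged called, DESeq2 12). Genes were drawn independently, so calls that come from a structure shared by samples are not covered. All 84 libraries were used.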

Results

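RNA was sequenced from sorted blood progenitors of mice that carry a tetracycline-regulated transgene for MLL-ENL, a fusion of the human genes KMT2A and MLLT1 that occurs in acute leukemia, and from control mice whose genotype was labelled wild type. The study asks at which age induction of MLL-ENL starts leukemia most readily. The 84 libraries, 43 from control and 41 from MLL-ENL mice, fell into 22 groups by age, population and genotype. The populations were HPC, labelled as committed hematopoietic progenitor cells, pGM, the pre-granulocyte-monocyte progenitors, and GMP, the granulocyte-monocyte progenitors that follow them. All 3 were sorted from neonatal liver on the day of birth (P0) and from bone marrow at 10 weeks, without doxycycline, which the labels call fetal induction. HPC alone were taken from bone marrow at 6 and 12 months with an 8 week doxycycline label and the note adult induction. A separate set of 10 week libraries compared mice labelled MLL-ENL (x2) with controls of their own. What x2 stands for is not given in the sources used here. Groups held 4 libraries, except the P0 pGM controls and the 3 MLL-ENL (x2) groups, with 3 each. Libraries held 7.62 to 29.47 M counts, with a median of 14.75 M. Levels are TMM-scaled CPM with SD, and changes are log2 fold changes with SE. Levels of the transgene, Xist and Ddx3y are the exception: they are CPM of mouse counts without TMM scaling. Genes named below for their size of change showed no overlap between the libraries of the compared groups.

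Reads on the human transgene, the sum of human KMT2A and MLLT1, were found in all 41 MLL-ENL libraries, with at least 6 counts (0.44 CPM) in each. Most lay on KMT2A, with 861 counts against 31 on MLLT1 in P0 MLL-ENL HPC and 144 against 0 at 6 months. Among the 43 control libraries the highest had 8 counts (0.62 CPM) and 12 had 0. Above this highest control lay 40 of the 41 MLL-ENL libraries, the exception being 10 week GMP 74 at 0.44 CPM, where the controls of its group reached 0.21 CPM. At P0 the transgene stood at 15.57 ± 3.87 CPM in HPC, 10.65 ± 1.4 CPM in pGM and 5.03 ± 2.38 CPM in GMP (SD, n = 4 each). At 10 weeks it stood at 4.62 ± 1.92, 3.0 ± 2.23 and 1.77 ± 1.74 CPM in the same populations (n = 4 each). The pGM mean was 1.90 CPM without the library labelled 73 and the GMP mean 0.92 CPM without 78. With the libraries labelled 73 exchanged, a change chosen after seeing the data, the means were 5.27 CPM in HPC and 2.35 CPM in pGM. The MLL-ENL (x2) groups had 10.92 ± 3.29, 7.56 ± 2.30 and 6.88 ± 3.90 CPM (n = 3 each), and HPC had 2.46 ± 1.21 CPM at 6 months and 4.04 ± 1.25 CPM at 12 months (n = 4 each). The P0 mean in HPC was 3.37 times that at 10 weeks (2-sided exact permutation p = 0.029, the smallest possible; adjusted p = 0.12 over 13 comparisons). MLL-ENL (x2) HPC had 2.36 times the mean of MLL-ENL HPC at 10 weeks (exact p = 0.057, the smallest possible; adjusted p = 0.15), and none of the 13 comparisons passed the adjustment. The mouse counterparts of the fused genes did not change in any of the 11 comparisons of genotypes: log2 fold changes of Kmt2a ran from -0.23 to 0.39 and those of Mllt1 from -0.47 to 0.40, with adjusted p from 0.39 to 1.

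**Figure D1:**
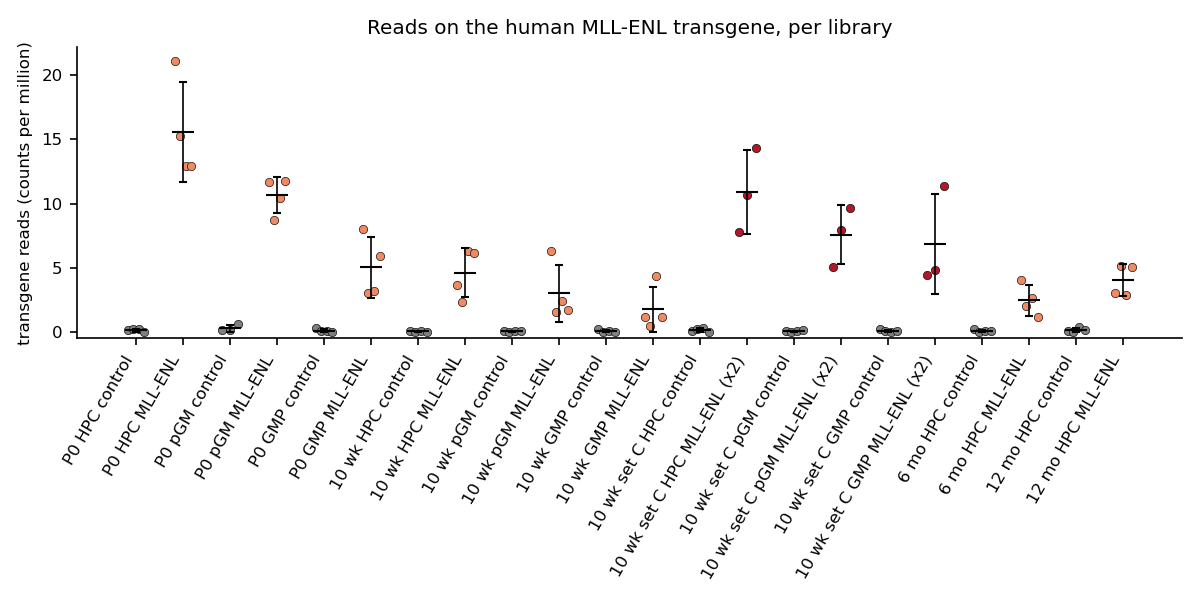
Reads on the human MLL-ENL transgene in each of the 84 libraries (y axis, CPM of mouse counts; grey control, orange MLL-ENL, red MLL-ENL (x2); bars, mean and SD). Every control library lies at or below 0.62 CPM, and the group means of MLL-ENL libraries run from 1.77 CPM in 10 week GMP to 15.57 CPM in P0 HPC.

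In neonatal HPC, Skida1, Mecom, Meis1 and several Hoxa genes were higher in MLL-ENL libraries. Skida1 stood at 25.1 ± 2.04 CPM against 1.48 ± 0.942 CPM in controls (SD, n = 4 each; log2 fold change 4.09 ± 0.49, adjusted p = 4.6e-07). Mecom, a transcription factor of stem cells also known as Evi1, stood at 172 ± 27.3 against 25.6 ± 4.49 CPM (2.75 ± 0.36, 1.9e-06). Hoxa9, a homeobox gene that sustains progenitor self-renewal, was at 70.2 ± 11.8 against 31.0 ± 4.35 CPM (1.18 ± 0.22, 0.00055), and its cofactor Meis1 at 598 ± 68.8 against 276 ± 25.6 CPM (1.11 ± 0.22, 0.0011). Hoxa2, Hoxa3, Hoxa5, Hoxa7 and Hoxa10 rose as well, by 1.0 to 2.60 on the log2 scale. Of the 23 measured MLL fusion targets 8 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.70, camera adjusted p = 3.2e-10, and adjusted p = 0.01 with an estimated correlation). The receptor Il9r (3.39 ± 0.58), the transporter Slc16a11 (3.37 ± 0.59), the protocadherin Pcdh7 (2.86 ± 0.35), the matrix protein Postn (3.16 ± 0.65), and Pak3, Ndnf, Plekhb1 and the growth factor Igf2 completed the 10 largest rises (adjusted p up to 0.015). The stem and multipotent progenitor list went up (median 0.49, adjusted p = 0.002; adjusted p = 0.16 with an estimated correlation), with 5 of 20 members up, among them Angpt1 and Hoxb5, and 2 down, among them Cd34 (-0.74 ± 0.18). Adjusted over the list alone 6 rose and 2 fell. Of the fetal and neonatal list 5 of 17 members rose and 1 fell by either adjustment, with Lin28b (1.43 ± 0.29) and Igf2bp2 (1.11 ± 0.26) among the rises. The list median was 0.46 (camera adjusted p = 0.027, but 0.12 and not called with an estimated correlation).

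Antigen presentation, mast cell and cell cycle genes fell in the same neonatal HPC. H2-Ab1, a chain of MHC class II, stood at 250 ± 150 CPM against 1940 ± 768 CPM in controls (SD, n = 4 each; log2 fold change -2.96 ± 0.38, adjusted p = 1.5e-06). The protease inhibitor Cst3, abundant in dendritic cells, stood at 711 ± 169 against 4050 ± 1320 CPM (-2.51 ± 0.20, 4.3e-11). Of the 10 MHC class II genes 8 fell (9 adjusted over the list alone; median -2.11, camera adjusted p = 1.5e-19, and adjusted p = 0.00077 with an estimated correlation). The monocyte and dendritic list lost 11 of 20 (15 adjusted over the list alone; median -1.81, 6.5e-14, and adjusted p = 0.01 with an estimated correlation), with Psap at -1.74 ± 0.27, Lgals3 at -2.91 ± 0.54 and Mpeg1 at -2.85 ± 0.56. The mast cell protease Mcpt4 stood at 0.305 ± 0.314 against 23.0 ± 14.4 CPM (-6.18 ± 1.05, 0.00024). Tpsab1 (-4.60 ± 0.77), Tpsb2 (-4.25 ± 1.03), Cma1 (-4.03 ± 0.85) and the serotonin enzyme Tph1 (-4.44 ± 0.88) were also among the 10 largest falls. Cpa3, the mast cell carboxypeptidase, was at 15.8 ± 5.77 against 168 ± 74.0 CPM, and 6 of 14 mast cell and basophil genes fell by either adjustment (median -2.06, adjusted p = 1.8e-05; adjusted p = 0.097 with an estimated correlation). The other 5 of the 10 largest falls were Dnase1l3 (-4.06 ± 0.65), the integrin Itgae (-4.01 ± 0.59), the chemokine receptor Xcr1 (-3.89 ± 0.76), the receptor Klrk1 (-3.78 ± 0.72) and Gpr141b (-3.61 ± 0.96), with adjusted p from 1.9e-05 to 0.015.

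Mitosis genes fell in P0 HPC in 14 of 20 cases (18 adjusted over the list alone; median -0.68, camera adjusted p = 2.8e-13, and adjusted p = 0.017 with an estimated correlation), Birc5 from 154 ± 30.1 to 85.0 ± 15.1 CPM and Cdk1 by -0.69 ± 0.16. DNA replication genes fell in 9 of 22 (16 adjusted over the list alone; median -0.54, adjusted p = 2.1e-08; adjusted p = 0.067 with an estimated correlation), among them Pola1 (-0.78 ± 0.19) and Rrm2 (-0.90 ± 0.23). Ribosome biogenesis lost 3 of 20 (11 adjusted over the list alone; median -0.43, 6.9e-06; adjusted p = 0.16 with an estimated correlation), Npm1 and Fbl among them. Oxidative phosphorylation lost 3 of 22 (7 adjusted over the list alone; median -0.39, 3.7e-05; adjusted p = 0.16 with an estimated correlation). Sorting antigens had 4 of 10 down by either adjustment, Fcgr2b (-1.74 ± 0.28), Fcgr3, Cd34 and Cd48, and the list test did not pass (adjusted p = 0.062). Lists that did not pass either were neutrophil granule (median -0.31, adjusted p = 0.31), T and NK cell (-0.25, 0.61), erythroid (-1.04, 0.35), megakaryocyte (0.46, 0.063), type I interferon response (0.20, 0.1) and p53 response (-0.12, 0.49). The immediate early (0.27, 0.5), hepatocyte (-0.75, 0.49), and stroma and endothelium (0.28, 0.15) lists did not pass, nor did lymphoid priming (median 0.12, mean -0.04, 0.61) and inflammatory NF-kB (median 0.05, mean -0.08, 0.72), whose median and mean differ in sign. Single members that did included Ctsg (-2.31 ± 0.59), Klrd1 (-2.56 ± 0.61), Pf4 (-1.44 ± 0.47) and the p53 target Pmaip1 (-1.20 ± 0.38), lower, and the embryonic globin Hbb-bh1 (4.36 ± 1.0), Gp9, Pecam1 and Bgn, higher. In all, 361 genes were higher and 772 lower of 14899 tested (edgeR, 4 against 4 libraries). Sex was not balanced between genotypes at P0 and was not fitted. Among HPC controls 2 libraries held transcripts of both sexes and 2 those of the Y chromosome alone. Of the MLL-ENL HPC libraries 3 held both and 1 Xist alone (floor 5 CPM). P0 pGM and GMP were skewed in the same direction. Leaving out control 2, MLL-ENL 4 or MLL-ENL 5 gave 693, 604 and 624 genes, and RLE scaling moved the balance to 421 higher and 582 lower.

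**Figure D2:**
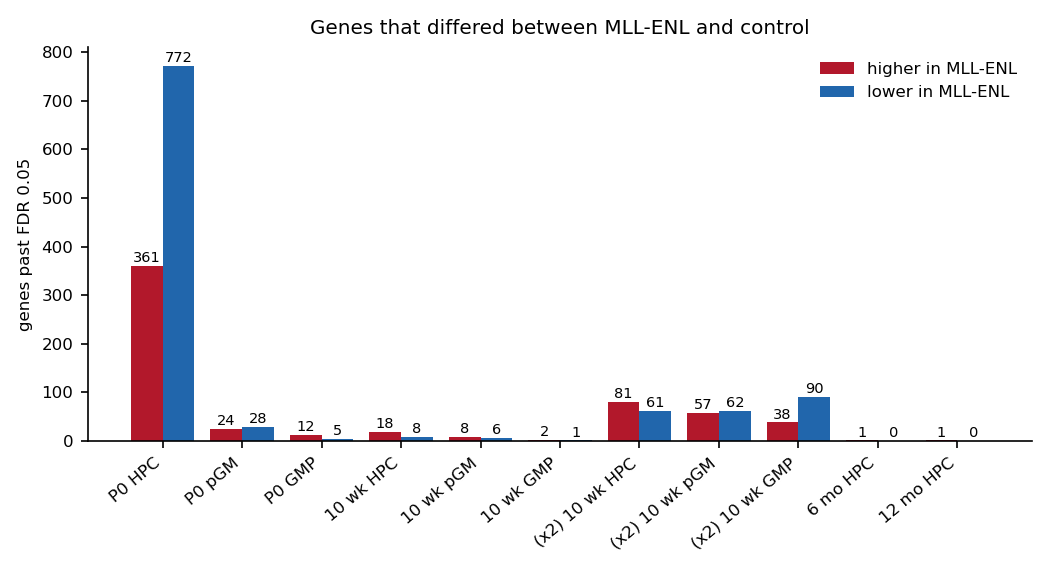
Genes past FDR 0.05 in the 11 comparisons of MLL-ENL with control (y axis, number of genes; red higher in MLL-ENL, blue lower). P0 HPC stands apart with 361 and 772 genes, the MLL-ENL (x2) groups follow with 119 to 142 in total, and 6 and 12 month HPC have 1 each.

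Neonatal pGM shared some of the rises of neonatal HPC, with Skida1 and Mecom at lower levels than there. Of the Hoxa genes that rose in HPC, Hoxa9 and Hoxa10 alone were called in pGM. Skida1 was at 14.3 ± 1.37 CPM against 0.805 ± 0.255 CPM (SD, n = 4 and 3; log2 fold change 4.14 ± 0.57, adjusted p = 4.1e-05), Mecom at 27.5 ± 3.54 against 3.22 ± 0.474 CPM (3.09 ± 0.43, 4.1e-05). Il9r (3.51 ± 0.69), Pcdh7 (2.72 ± 0.39), Hoxa10 (1.95 ± 0.41), the nuclear receptor Hnf4a (1.81 ± 0.33) and Hoxa9 (1.42 ± 0.25) rose. Chil5, Ddx4 and Cela1 were the other risers among the largest. Falls included the MHC class II genes H2-Eb1 (-2.45 ± 0.52), Cd74 (-2.27 ± 0.53) and H2-Aa (-2.24 ± 0.53). Lower too were the microglia and macrophage gene Aif1 (-2.43 ± 0.57), the semaphorin receptor Nrp1 (-2.96 ± 0.68), Naaa, Rnd3, Tfec, Dgkg, and C1qtnf6 (-1.86 ± 0.28, 0.00014), which encodes a secreted protein of the C1q and TNF family. MLL fusion targets rose in 4 of 23 (6 adjusted over the list alone; median 0.31, camera adjusted p = 1.7e-08, and adjusted p = 0.032 with an estimated correlation), Meis1 among them (1.15 ± 0.24). The monocyte and dendritic list was lower as a group (median -0.93, 1.9e-11, and adjusted p = 0.032 with an estimated correlation) with 0 of 20 members past the test over all genes and 3 adjusted over the list alone. MHC class II had 3 of 10 down (6 adjusted over the list alone; median -0.84, 8.3e-07; adjusted p = 0.078 with an estimated correlation). Neutrophil granule (median -1.29, adjusted p = 2.8e-05; adjusted p = 0.22 with an estimated correlation) and erythroid genes (median 1.27, 1.5e-06; adjusted p = 0.21 with an estimated correlation) had no member past the test over all genes, and 1 lower and 6 higher adjusted over the list alone. In total 24 genes were higher and 28 lower. With replicate numbers as a block 57 rose and 101 fell and the erythroid median was 0.14 (adjusted p = 0.88), and without control 2, control 3, MLL-ENL 4 or MLL-ENL 5 the count was 22, 24, 26 and 34. DESeq2 called 103.

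Neonatal GMP had 12 genes higher and 5 lower. Cpvl, a carboxypeptidase of the myeloid lineage, went from 0.525 ± 0.312 to 30.6 ± 15.7 CPM (SD, n = 4 each; log2 fold change 5.87 ± 0.71, adjusted p = 2e-06). Hoxa9 went from 6.83 ± 1.72 to 26.0 ± 4.26 CPM (1.92 ± 0.23, 1.6e-06), and Hoxa7 (1.33 ± 0.17), Hoxa10 (2.81 ± 0.45), Meis1 (1.38 ± 0.23), Pcdh7 (2.49 ± 0.36), Hnf4a (2.01 ± 0.30), H2-Ob and Pkib rose. The MHC class II list as a whole did not pass (median 0.21, mean -0.18, adjusted p = 0.33; 1 up over all genes, 4 up and 3 down adjusted over the list alone). C1qtnf6 (-1.76 ± 0.27, 0.00014), Plxdc2, Maged1 and the interferon-induced membrane protein Ifitm1 (-1.04 ± 0.23) fell. MLL fusion targets rose in 4 of 23 (5 adjusted over the list alone; median 0.12, mean 0.47, camera adjusted p = 9.5e-08, and adjusted p = 0.048 with an estimated correlation). Mitosis genes were lower as a group (median -0.46, 4e-14, and adjusted p = 0.042 with an estimated correlation), with 0 of 20 past the test over all genes and 10 adjusted over the list alone, Top2a at -0.64 ± 0.19. With the block 100 genes rose and 57 fell, without control 3 the count was 11, the 2 groups fitted alone gave 10, and DESeq2 called 39.

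At 10 weeks the libraries labelled MLL-ENL 73 stood apart from their groups. A score of HPC against pGM used up to 50 marker genes of each population, chosen from the controls of the MLL-ENL (x2) set. It was -1.42 in the library labelled 73 HPC and 2.64 to 3.15 in the other 3 MLL-ENL HPC libraries. It was 2.89 in the library labelled 73 pGM against -1.87 to -1.45 in the other 3 MLL-ENL pGM libraries. Each value therefore lay among those of the other population. Values without both libraries, an alternative chosen after seeing the data, are given beside the counts of genes at 10 weeks in HPC and pGM.

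**Figure D3:**
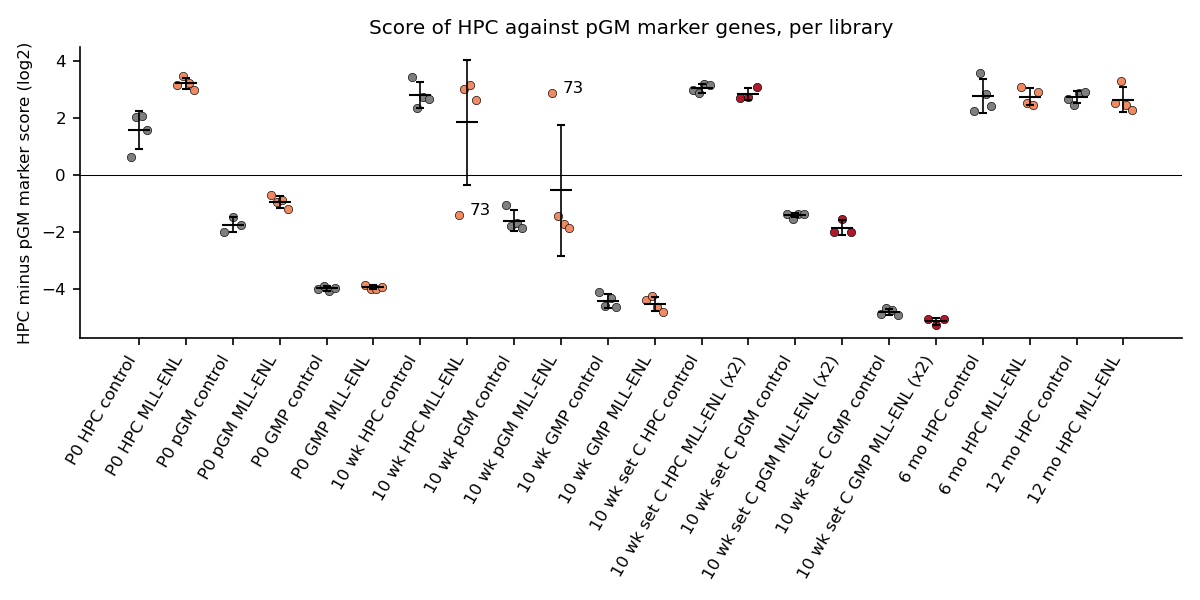
Score of HPC against pGM marker genes in each library (y axis, log2 units; points as in the plot of transgene reads, bars mean and SD, numbers mark the libraries labelled 73). The library labelled 73 HPC lies at -1.42 with the pGM libraries and the one labelled 73 pGM at 2.89 with the HPC libraries.

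In 10 week HPC, 18 genes were higher and 8 lower. Tifab, a regulator of TRAF6 signalling, stood at 156 ± 96.4 CPM against 23.3 ± 6.03 CPM (SD, n = 4 each; log2 fold change 2.74 ± 0.39, adjusted p = 5.9e-05). Pcdh7 rose by 2.49 ± 0.38, the leukotriene enzyme Alox5 by 3.44 ± 0.73 and the endosomal protein Ehd3 by 2.35 ± 0.50, with Ccr1, Lgals1, Fcer1g and the Rosa26 transcript Gt(ROSA)26Sor (1.14 ± 0.21) also higher. The kelch-like gene Klhl4 was at 0.545 ± 0.792 against 13.7 ± 2.02 CPM (-4.64 ± 0.57, 2e-06), C1qtnf6 at 5.11 ± 1.64 against 22.8 ± 4.21 CPM (-2.15 ± 0.27, 2e-06). The platelet protein Mmrn1 (-2.96 ± 0.44), the endotoxin receptor Cd14 (-3.75 ± 0.79), Slc35d3, Rftn2 and Epb41l5 fell. Chosen after their values were seen, Il9r (6.71 ± 0.81, 2e-06), Skida1 (4.52 ± 0.71, 0.00027) and Sva (7.76 ± 0.79, 3.8e-07) rose too. Without the libraries labelled 73 the count was again 26, with 19 genes shared: Tifab (2.20 ± 0.32), Pcdh7, Alox5, Ehd3, Klhl4, C1qtnf6, Mmrn1 and Rftn2 stayed past the test. Ccr1 went to 1.55 ± 0.38 from 1.74 ± 0.38, Lgals1 to 0.81 ± 0.19 from 1.34 ± 0.27 and Cd14 to -3.84 ± 0.89. Slc35d3 went to -1.71 ± 0.41 from -1.95 ± 0.40 and Epb41l5 to -1.48 ± 0.39 from -1.63 ± 0.36. These 5 calls were lost at an adjusted p of 0.055 to 0.12 with 1 library fewer, Lgals1 with a smaller change and the others with folds close to those before. Hoxa9 (0.37 ± 0.22), Meis1 (-0.02 ± 0.22) and the other MLL fusion targets had 0 of 23 past the test over all genes. Adjusted over the list alone 2 were higher (median 0.16, camera adjusted p = 0.0045, but 0.37 with an estimated correlation). The library labelled 73 HPC had the lowest Hoxa9 and Meis1 of its group, at 26.8 and 379 CPM. The others had 32.6 to 49.5 and 489 to 714 CPM. Without the libraries labelled 73 the list median was 0.11 (camera adjusted p = 0.0043, but 0.44 with an estimated correlation). Mast cell and basophil genes had a median of 1.26 (1.6e-06; adjusted p = 0.079 with an estimated correlation; 0 of 14 past the test over all genes, 4 higher adjusted over the list alone). It was 0.57 without the libraries labelled 73 (0.00029; adjusted p = 0.44 with an estimated correlation). The monocyte and dendritic median of 0.71 (0.0037; adjusted p = 0.48 with an estimated correlation) turned to -0.20 without them. Mitosis genes had a median of -0.32 (8.8e-11; adjusted p = 0.079 with an estimated correlation; 0 of 20 past the test by either adjustment). Leaving out control 76 gave 17 genes, a fit of the 2 compared groups alone 7, no filter on low counts 42, and DESeq2 59.

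In 10 week pGM, 8 genes were higher and 6 lower. C1qtnf6 fell from 28.3 ± 4.60 to 3.86 ± 1.12 CPM (SD, n = 4 each; log2 fold change -2.88 ± 0.27, adjusted p = 5.4e-09) and Cd14 from 26.5 ± 3.52 to 2.51 ± 1.13 CPM (-3.41 ± 0.70, 0.022). Ehd3 (3.01 ± 0.52), Slc16a11 (2.55 ± 0.52), Mecom (1.70 ± 0.35), the prostacyclin receptor Ptgir and Hnf4a (1.49 ± 0.29 each) rose. Chosen after their values were seen, Klhl4 fell (-5.74 ± 0.71, 2.2e-06), and Il9r (5.85 ± 0.79, 1.7e-05) and Sva (6.46 ± 0.66, 2e-07) rose. Without the libraries labelled 73 the count was 7, with 5 genes shared, C1qtnf6 (-2.85 ± 0.30) and Ehd3 (2.76 ± 0.53) among them. Cd14 went to -3.13 ± 0.77 and Tnfsf13os to -1.99 ± 0.43 from -2.04 ± 0.39, losing their calls with 1 library fewer and folds close to those before (adjusted p = 0.21 and 0.083). Slc16a11 went to 1.57 ± 0.45, Mecom to 1.18 ± 0.29, Ptgir to 1.14 ± 0.28 and Hnf4a to 1.06 ± 0.27, losing theirs with smaller changes (adjusted p = 0.62 for Slc16a11 and 0.21 for the other 3). Megakaryocyte genes were lower as a group (median -0.63, camera adjusted p = 0.00011, and adjusted p = 0.0039 with an estimated correlation), with 0 of 12 past the test over all genes and 1 adjusted over the list alone. Without the libraries labelled 73 the median was -0.71 (1.1e-05, and adjusted p = 0.0019 with an estimated correlation). Leaving out control 80, control 87 or the library labelled 73 gave 8, 9 and 6 genes, the 2 groups fitted alone 5, and DESeq2 40. In 10 week GMP, Prdm16, a stem cell transcription factor related to Mecom, rose from 4.56 ± 0.632 to 18.5 ± 6.64 CPM (2.03 ± 0.26, 1.4e-05). C1qtnf6 fell from 28 ± 2.03 to 3.77 ± 1.44 CPM (-2.86 ± 0.28, 8.9e-09). The third gene was Sva, a seminal vesicle antigen gene chosen after its values were seen, at 1.57 ± 0.738 against 0.0635 ± 0.0846 CPM, and DESeq2 called 10 genes.

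Mice labelled MLL-ENL (x2) showed more genes per population at 10 weeks, against controls of their own set. In HPC, Tifab stood at 311 ± 84.8 CPM against 24.4 ± 5.44 CPM (SD, n = 3 and 4; log2 fold change 3.67 ± 0.23, adjusted p = 3.6e-09). Ehd3 stood at 49.3 ± 9.87 against 2.84 ± 0.653 CPM (4.12 ± 0.37), and Pcdh7 at 18.8 ± 2.37 against 0.588 ± 0.390 CPM (5.01 ± 0.51). Chga (3.99 ± 0.47), a protein of secretory granules, the endothelin receptor Ednra, Nsg2, the signalling antagonist Spry4, Nrk, Rhbdf1 and Slc16a11 made up the 10 largest rises. Hoxa9 rose from 40.8 ± 6.98 to 99.8 ± 17.6 CPM (1.29 ± 0.18, 0.00039). With Hoxa5, Hoxa7, Hoxa10 and Mecom it made 5 of 22 MLL fusion targets up (7 adjusted over the list alone; median 0.44, camera adjusted p = 1.2e-12; adjusted p = 0.055 with an estimated correlation). Fetal and neonatal genes rose in 5 of 11 (6 up and 1 down adjusted over the list alone; median 0.82, 6.2e-09, and adjusted p = 0.00022 with an estimated correlation), among them Hmga2 (1.04 ± 0.17), Igf2bp2 (1.42 ± 0.25) and Lin28b, at 2.41 ± 0.497 against 0.0127 ± 0.0254 CPM. The basophil protease Prss34 fell from 32.0 ± 18.3 to 0.301 ± 0.152 CPM (-6.74 ± 0.77, 3.5e-05), the eosinophil granule protein Prg2 from 126 ± 65.9 to 7.27 ± 4.26 CPM (-4.11 ± 0.69), and C1qtnf6 from 23.9 ± 1.88 to 1.44 ± 0.877 CPM (-4.08 ± 0.33, 2.8e-07). Cd14, Mmrn1, the T cell and stem cell factor Gata3, Ptger3, Ces2g, Arhgef28 and Mmp2 were also among the 10 largest falls. Outside this ranking and chosen after their values were seen, Klhl4 fell (-6.97 ± 0.85, 5.9e-05) and Il9r rose (7.64 ± 0.84, 3.7e-05). Mast cell and basophil genes fell in 2 of 13 (3 adjusted over the list alone; median -1.26, 0.0014; adjusted p = 0.36 with an estimated correlation). The neutrophil granule list had a median of -2.26 with 1 of 20 down over all genes, and 3 up and 8 down adjusted over the list alone, and did not pass (adjusted p = 0.2). In all 81 genes were higher and 61 lower. In each population of this set 3 control libraries held Xist and 1 Y transcripts, against 1 and 2 of MLL-ENL (x2), and sex was not fitted. Leaving out MLL-ENL (x2) 5897 or 5900 gave 74 and 85 genes, a fit of the 2 groups alone 74, and DESeq2 275.

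In MLL-ENL (x2) pGM, C1qtnf6 fell from 25.8 ± 1.41 to 0.361 ± 0.190 CPM (SD, n = 4 and 3; log2 fold change -6.10 ± 0.39, adjusted p = 5.5e-09) and the scavenger receptor Scarf1 from 17.7 ± 2.42 to 2.13 ± 0.379 CPM (-3.04 ± 0.27, 1.2e-06). Prg2, Cd14, Tmem215, Mmp2, Mmrn1, Arhgef28, the cyclophilin Ppic (-2.33 ± 0.18) and the angiopoietin receptor Tek (-2.49 ± 0.40) were lower too. Chga (4.64 ± 0.51), Ehd3 (3.49 ± 0.37), the globin Hbb-bt (2.82 ± 0.44), Trbc2, Pcdh7, Slc16a11, Nsg2, Mrgpra2b, Dbn1 and Gem were the 10 largest rises. The fetal RNA-binding gene Igf2bp3 rose by 2.85 ± 0.49. Fetal and neonatal genes had 2 of 11 up and 1 down (4 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 0.00086, and adjusted p = 0.012 with an estimated correlation). The stem and multipotent progenitor list went down (median -0.34, 9.3e-07, and adjusted p = 0.012 with an estimated correlation) with 4 of 20 lower, Esam, Tek and Ifitm1 among them, and Mecom higher (1.51 ± 0.23). Adjusted over the list alone 8 fell and 1 rose. In total 57 genes were higher and 62 lower. Without MLL-ENL (x2) 5897 the count was 75, with the controls of both sets pooled 267, and by DESeq2 256.

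In MLL-ENL (x2) GMP, the mast cell and basophil list and the erythroid list were each lower as a group. Prss34 went from 164 ± 60.1 to 23.0 ± 9.98 CPM (SD, n = 4 and 3; log2 fold change -2.83 ± 0.55, adjusted p = 0.01), the IgE receptor chain Fcer1a from 13.2 ± 7.64 to 0.951 ± 0.198 CPM (-3.78 ± 0.83, 0.025). In all, 5 of 13 mast cell and basophil genes fell (9 adjusted over the list alone; median -1.97, camera adjusted p = 1.7e-13, and adjusted p = 0.015 with an estimated correlation). Erythroid genes fell in 2 of 18, Gata1 and Car2 (7 adjusted over the list alone; median -2.21, or -1.91 with genes absent from a group at their bound, 1.9e-10, and adjusted p = 0.031 with an estimated correlation). The stem and multipotent progenitor list went down (median -0.32, 2.9e-06, and adjusted p = 0.016 with an estimated correlation; 5 of 20 down and 1 up, 7 and 1 adjusted over the list alone), with Tek, Ifitm1 and Hlf lower and Mecom (1.48 ± 0.26) higher. Hoxa10 rose from 1.21 ± 0.481 to 7.28 ± 1.66 CPM (2.58 ± 0.26, 5.8e-06), Hoxa7 and Hoxa9 (1.07 ± 0.19) rose as well, and Igf2bp3 rose from 0.330 ± 0.0737 to 8.46 ± 4.31 CPM (4.65 ± 0.52, 3.4e-05). Hpgd, Ednra, Ckm, Prdm16 (1.93 ± 0.30), Cd33, Sgip1, Nrg4 and Cdk19 were further rises, and Hpgd spread from 2.35 to 103 CPM among the 3 MLL-ENL (x2) libraries. C1qtnf6 (-5.41 ± 0.37, 1.2e-08), Ppic (-3.34 ± 0.19), Gzmb, Scarf1, Ces2g, Cd55 and Ppp1r9a fell. In all 38 genes were higher and 90 lower. Leaving out control 4894, MLL-ENL (x2) 5897 or 5900 gave 68, 67 and 82 genes, the 2 groups fitted alone 44, and DESeq2 214.

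**Figure D4:**
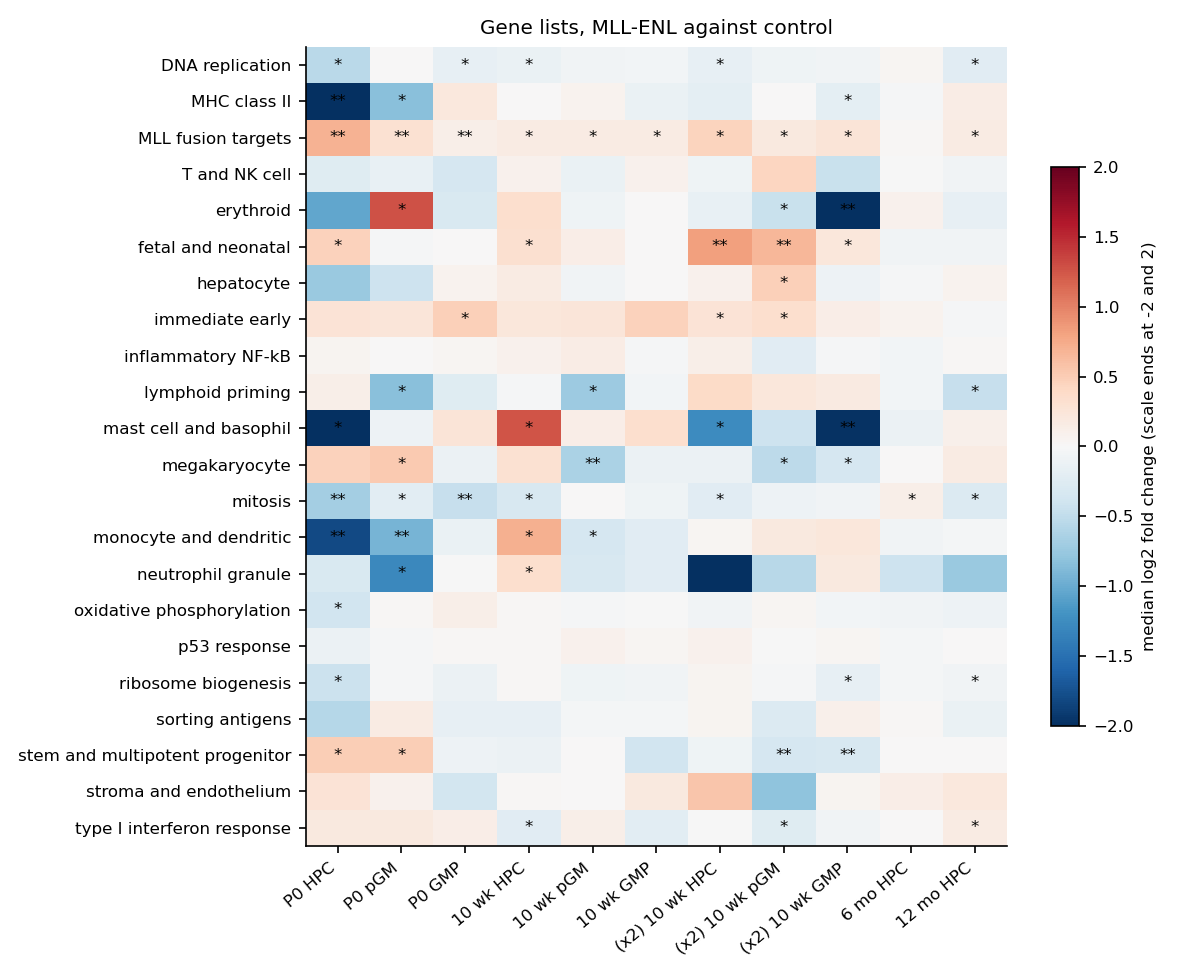
Median log2 fold change of MLL-ENL against control for the 22 gene lists (rows) in the 11 comparisons (columns). The colour scale ends at -2 and 2. A single star marks an adjusted p under 0.05 with the preset correlation and a double star also with an estimated one. The MLL fusion targets have a double star in the 3 P0 populations, with medians of 0.70, 0.31 and 0.12.

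After adult induction, 1 gene passed at each age in HPC, by edgeR over 13059 genes: Sva, chosen after its values were seen. Sva stood at 1.46 ± 0.159 CPM at 6 months and 1.97 ± 0.423 CPM at 12 months (SD, n = 4 each), and was called higher in all 11 comparisons of genotypes (adjusted p from 3.6e-10 to 0.0027). Over the whole series it ran from 1.04 to 6.29 CPM in MLL-ENL libraries, and in controls it was at 0 in 36 of 43 libraries and at most 0.179 CPM. C1qtnf6 stood at 29.2 ± 7.48 CPM against 29.7 ± 6.97 CPM at 6 months (log2 fold change -0.03 ± 0.20) and 31.9 ± 3.85 against 36.2 ± 8.78 CPM at 12 months (-0.18 ± 0.20). Klhl4 stood at 19.6 ± 2.09 against 17.8 ± 3.04 and 23.5 ± 3.97 against 23.5 ± 3.84 CPM. Mecom at 12 months was at 97.3 ± 8.77 against 63.0 ± 7.86 CPM (0.63 ± 0.15) and did not pass over all genes. It was the 1 MLL fusion target of 21 that rose adjusted over the list alone (median 0.16, camera adjusted p = 0.00051; adjusted p = 0.65 with an estimated correlation). Mitosis genes had medians of 0.11 at 6 months (0.0021; adjusted p = 0.91 with an estimated correlation) and -0.27 at 12 months (2e-08; adjusted p = 0.65 with an estimated correlation), with 0 of 20 members past the test at either age by either adjustment. Type I interferon genes had a median of 0.16 at 12 months (1.9e-05; adjusted p = 0.65 with an estimated correlation; 0 of 25 by either adjustment). Genes lower were 0 at both ages by edgeR, and DESeq2 called 4 and 15 in total. By edgeR 243 and 882 of 13059 genes in either direction had an unadjusted p under 0.05. Chance alone gives more than the former and fewer than the latter. With the 2 groups fitted alone the 12 month count was 0.

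The effect in HPC was tested directly between P0 and 10 weeks, and it differed for 53 genes that were higher and 185 that were lower at P0 relative to 10 weeks. Klhl4, lowered at 10 weeks, had a difference of 5.57 ± 0.73 on the log2 scale (SE; 4 groups of 4 libraries; adjusted p = 1.2e-05), and Mecom of 2.10 ± 0.48 (0.015). Differences the other way included Cpa3 (-5.78 ± 0.82, 4.3e-05), Cst3 (-2.77 ± 0.28, 2.9e-08), Alox5 (-5.33 ± 1.0), Ly86, Tcf7, Olfm1 and Nrp1. MHC class II genes differed in 6 of 10 (8 adjusted over the list alone; median -2.30, camera adjusted p = 3.7e-16, and adjusted p = 0.003 with an estimated correlation). Monocyte and dendritic genes differed in 10 of 20 (16 adjusted over the list alone; median -2.53, and adjusted p = 0.0054 with an estimated correlation), and mast cell and basophil genes in 4 of 14 (10 adjusted over the list alone; median -3.75, and adjusted p = 0.012 with an estimated correlation). Without the libraries labelled 73, 153 genes differed, 129 of them shared, and the medians of these 3 lists were -2.24, -1.49 and -3.15. Klhl4 (5.23 ± 0.68), Cpa3 (-4.28 ± 0.54), Cst3 (-2.57 ± 0.27) and Mecom (1.86 ± 0.39) kept their calls. Meis1 lost its call with a fold close to that before, 1.06 ± 0.30 from 1.14 ± 0.31 (adjusted p = 0.077). The others lost theirs with smaller differences: Car1 at -3.85 ± 1.08 from -5.52 ± 1.30 (0.076), F13a1 at -2.27 ± 0.70 from -5.87 ± 1.27 (0.12), Gata1 at -1.90 ± 0.65 from -3.83 ± 0.98 (0.17) and Mpo at -1.12 ± 0.41 from -2.68 ± 0.70 (0.21). With a wider spread as well, March1 was at -2.26 ± 1.55 from -4.78 ± 1.18 (0.54) and Ifi205 at -2.12 ± 1.77 from -4.85 ± 1.33 (0.64). The count was 120 without P0 control 2, 137, 123 and 146 without P0 MLL-ENL 3, 4 and 5, 118 and 120 without 10 week controls 76 and 87, and 116 without the library labelled 73. The 4 groups fitted alone gave 133, and DESeq2 375.

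In pGM the difference between P0 and 10 weeks passed for Klhl4 alone, chosen after its values were seen, and in GMP for Prdm16 (-2.53 ± 0.36, adjusted p = 0.0003), at 8.66 ± 1.92 against 12.3 ± 1.70 CPM in P0 GMP. Without the libraries labelled 73 each count was 2, RLE scaling gave 2 in pGM, and DESeq2 called 15 and 7. The pGM count was also 2 without P0 control 2, 3 or 5, P0 MLL-ENL 2, 10 week control 76 or 80, or 10 week MLL-ENL 78. Megakaryocyte genes differed as a group in pGM (median 1.0, camera adjusted p = 2.9e-06, and adjusted p = 0.0005 with an estimated correlation; 0 of 12 over all genes, 2 adjusted over the list alone). The MLL-ENL (x2) effect differed from the MLL-ENL effect at 10 weeks for 0 genes in HPC by edgeR, 9 by DESeq2 and 1 without control 4892. By edgeR 330 of 13601 genes had an unadjusted p under 0.05, fewer than chance alone gives at that threshold. The effects differed for C1qtnf6 (-3.21 ± 0.37, 0.0021) and Prg2 (-6.31 ± 0.93, 0.024) in pGM, and for Igf2bp3 (5.31 ± 0.69, 0.0053) in GMP. The pGM count was 1 without 10 week control 76, 87 or 88, control 4894, or MLL-ENL (x2) 5897 or 5900, and the GMP count 2 without 10 week control 80 or MLL-ENL 78. Mast cell and basophil genes differed as a group in HPC (median -3.29, 4.8e-17, and adjusted p = 0.00024 with an estimated correlation; 0 of 13 over all genes, 6 adjusted over the list alone). The count in HPC was again 0 without the libraries labelled 73 (edgeR; 539 at an unadjusted p under 0.05), and the median of this list was -3.33 (4.6e-14, and adjusted p = 0.0097 with an estimated correlation). In pGM it was 3, with C1qtnf6 at -3.26 ± 0.39 (0.0028) and Prg2 at -6.43 ± 0.94 (0.022). Genotype label and set of libraries change together in these comparisons, so the differences cannot be assigned to either. Between 6 and 12 months the effect in HPC differed for 0 genes by edgeR and 1 by DESeq2. By edgeR 333 of 13059 genes had an unadjusted p under 0.05, again fewer than chance alone gives. Between 10 weeks and 6 months the effect in HPC differed for Klhl4 alone (-4.80 ± 0.68, 0.028). The count was 0 without 10 week control 80, 87 or 88, MLL-ENL 78, 6 month control 1713, 1715 or 1717, or 6 month MLL-ENL 1709 or 1485. It was 3 without 10 week control 76, the library labelled 73, or 6 month MLL-ENL 1704 or 1714, and 3 without both libraries labelled 73.

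Calls recurred across ages and populations. Besides Sva, C1qtnf6 fell in 9 of 11 comparisons of genotypes, the exceptions being 6 and 12 months, Skida1 rose in 7, Hnf4a, Hoxa10, Il9r, Mecom and Pcdh7 in 6, and Cd14 fell in 6. The populations of 1 age and set came from animals with the same identifiers, so these comparisons are not independent. P0 HPC and P0 pGM, which share animals in this way, had 21 genes up and 17 down in common. P0 HPC and 10 week HPC shared 7 up and 3 down (0.44 and 0.41 by chance), with r = -0.06 for the log2 fold changes over genes, which are not independent replicates. P0 HPC and MLL-ENL (x2) HPC shared 31 and 21 (1.8 and 3.1 by chance) with 5 opposite (r = 0.27), and 10 week HPC and MLL-ENL (x2) HPC 10 and 6 (0.094 and 0.035 by chance; r = 0.19). For 10 week HPC r was -0.12 with 6 months and -0.09 with 12 months, and Sva was the 1 gene shared. Over the 16 pairs without shared animals 132 calls shared a direction and 5 were opposite, and over the 9 pairs with shared animals 209 and 1.

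**Figure D5:**
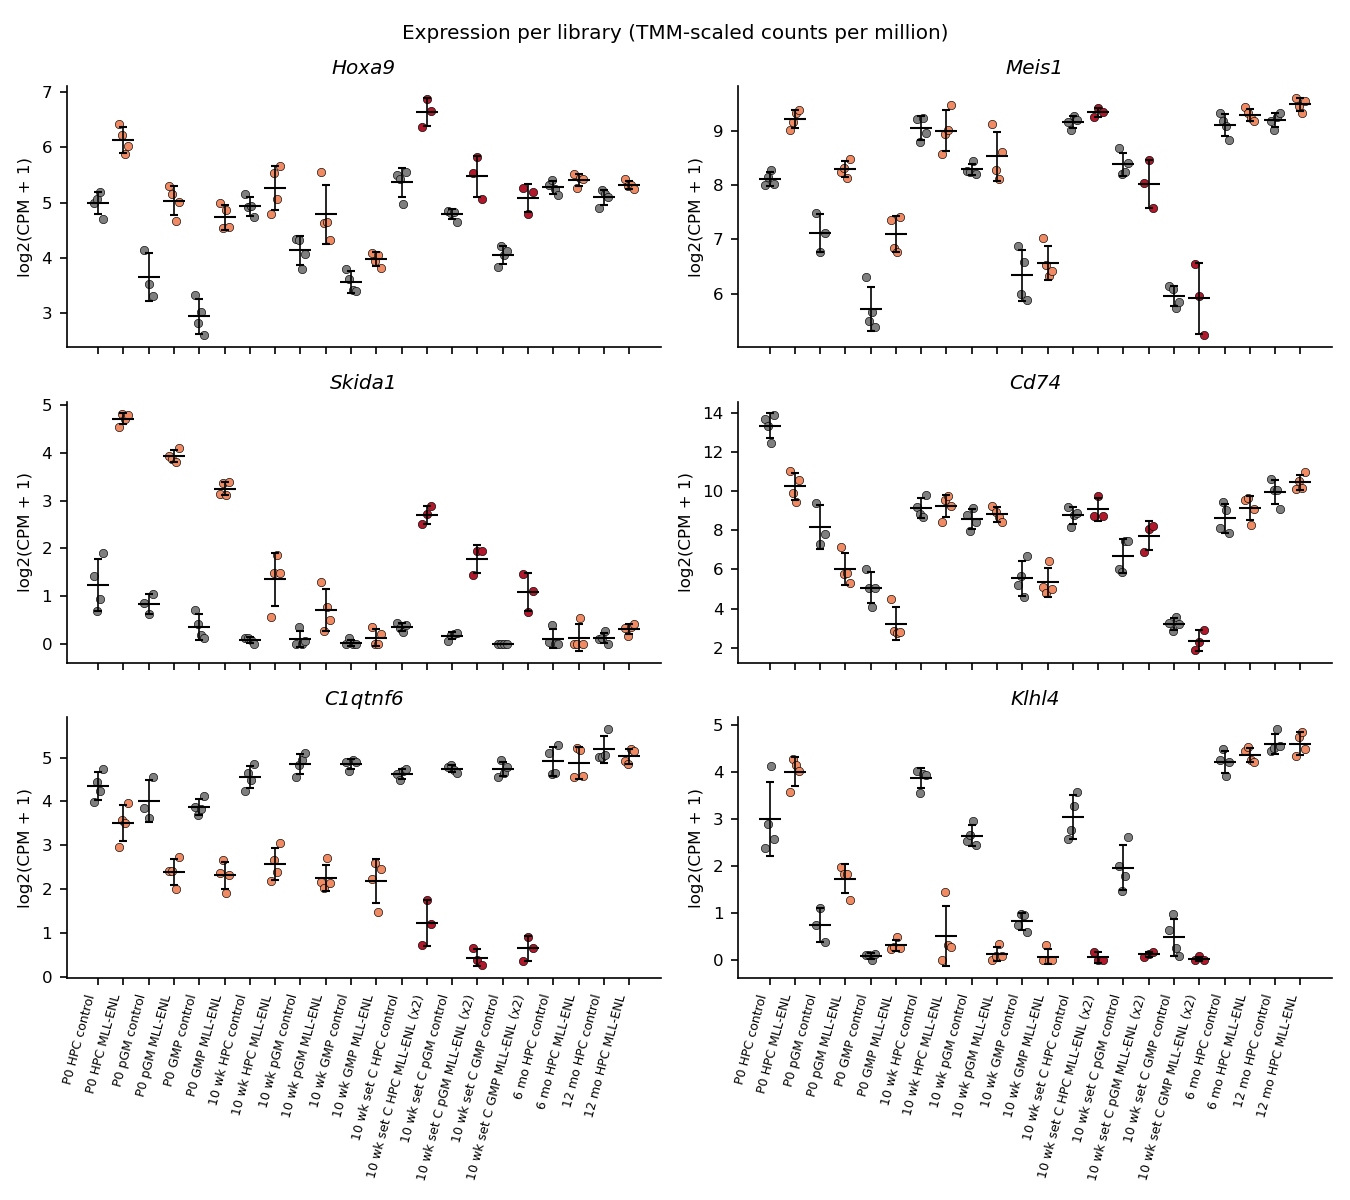
Levels of 6 genes in each library (y axis, log2 of CPM + 1; points as in the plot of transgene reads, bars mean and SD). C1qtnf6 lies lower in MLL-ENL than in control groups at P0 and 10 weeks and not at 6 or 12 months. Klhl4 is lost from 10 week MLL-ENL HPC (0.545 CPM) and kept in P0 HPC, and Cd74 is highest in P0 HPC controls (11200 CPM).

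Control progenitors differed between P0 and 10 weeks, where age and tissue changed together, from neonatal liver to bone marrow. In HPC, 1341 genes were higher and 1084 lower at P0 than at 10 weeks (edgeR, 4 against 4 libraries). Igf2bp3 stood at 92.3 ± 6.58 CPM against 1.01 ± 0.661 CPM (SD, n = 4 each; log2 fold change 6.46 ± 0.38, adjusted p = 3e-16). Hmga2, a chromatin protein of fetal stem cells, stood at 127 ± 24.5 against 12.1 ± 1.79 CPM. Fetal and neonatal genes rose in 14 of 17 by either adjustment (median 3.40, camera adjusted p = 5.7e-39, and adjusted p = 1.5e-11 with an estimated correlation). MHC class II genes were higher in 7 of 10 and lower in 1 by either adjustment (median 2.47, 3.1e-08, and adjusted p = 0.029 with an estimated correlation), Cd74 at 11200 ± 4160 against 589 ± 224 CPM. Monocyte and dendritic genes were higher in 13 of 20 (15 adjusted over the list alone; median 2.39, 1.7e-12, and adjusted p = 0.02 with an estimated correlation). Ifi205, Tlr11, Adora3, Cd36 and Id3 were among the largest rises. Hepatocyte genes were higher in 8 of 11 and lower in 2 by either adjustment (median 3.19, 7.9e-06, and adjusted p = 0.02 with an estimated correlation). Alb stood at 3.21 ± 0.994 CPM and at 0 at 10 weeks, at least 65.1-fold higher at P0 against a floor of 3 counts over the group. Dntt, the lymphoid polymerase of receptor gene joining, stood at 5.97 ± 4.49 against 1490 ± 231 CPM (-7.94 ± 0.51, 4.2e-15), and the MHC class I gene H2-Q7 at 1.12 ± 0.553 against 82.0 ± 17.2 CPM. The immunoglobulin segments Ighv11-2, Igkv12-44 and Iglc2 were at 0 at P0, at least 7560-fold, 1730-fold and 980-fold lower. Igkv12-44 and Iglc2 were also lower in the 10 week HPC controls of the MLL-ENL (x2) set than in those used here (-11.2 ± 0.91 and -6.56 ± 0.84). Their differences at P0 can therefore not be assigned to age and tissue rather than to these 10 week controls.

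In pGM, 771 genes were higher and 594 lower at P0, and in GMP 1184 and 639. Lin28b stood at 20.6 ± 2.55 CPM in P0 pGM (SD, n = 3) and at 0 at 10 weeks, at least 497-fold higher. Fetal and neonatal genes rose in 14 of 17 in pGM and 13 of 17 in GMP by either adjustment (medians 2.53 and 2.46, the latter 1.98 at the bound; camera adjusted p = 3e-41 and 3.9e-28, and adjusted p = 3.1e-12 and 6.3e-10 with an estimated correlation). Erythroid genes rose in 13 of 19 in P0 pGM (14 adjusted over the list alone; median 2.62, 1e-11, and adjusted p = 0.045 with an estimated correlation), the erythrocyte membrane protein Rhag at 148 ± 78.5 against 1.60 ± 1.13 CPM, with Hba-a1, Alas2 and Pklr among the largest rises. Hepatocyte genes rose in 7 of 11 in pGM and fell in 2 by either adjustment (median 4.91, or 3.96 at the bound; 1.3e-07, and adjusted p = 0.0097 with an estimated correlation). In P0 GMP the stefin Stfa1 stood at 1230 ± 935 CPM and at 0 at 10 weeks, at least 20800-fold higher, and the mast cell tryptase Tpsab1 at least 1880-fold higher. The neutrophil granule proteins Ltf (8.36 ± 1.30) and Camp (7.60 ± 1.20) rose. As a list, neutrophil granule genes rose in 9 of 19 by either adjustment (median 0.32, adjusted p = 0.0069; adjusted p = 0.44 with an estimated correlation). H2-Q7, H2-Q6, Esr1 and the haptoglobin receptor Cd163 were among the largest falls in both populations. Leaving out P0 control 3 or 5 in pGM gave 765 and 812 genes, and P0 control 5 in GMP 1145; the 2 GMP groups fitted alone gave 1054.

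Control HPC at 12 months had 55 genes higher and 18 lower than at 6 months. The 6 month control 1618 held transcripts of both sexes (Xist 26.9 and Ddx3y 33.8 CPM), as did the 12 month control 9806 (26.7 and 58.2 CPM). Cap1, an actin regulator, stood at 605 ± 27.9 CPM against 202 ± 9.64 CPM (SD, n = 4 each; log2 fold change 1.58 ± 0.08, adjusted p = 9.7e-09) and the retinaldehyde dehydrogenase Aldh1a1 at 13.9 ± 2.20 against 2.62 ± 1.07 CPM (2.38 ± 0.26, 0.00047). Clec1a, Aspa, St6gal1, Gata1 and Sdc2 rose, and the ribosomal genes Rps4l, Rps10 and Rpl27a, the IL-3 receptor chain Il3ra, Serpinh1 and Ptprcap fell. Mitosis genes had a median of 0.22 (camera adjusted p = 3.6e-05; adjusted p = 0.56 with an estimated correlation; 1 of 20 up, Prc1, and 4 adjusted over the list alone). Each of the 8 libraries moved the count past 1.5 times when left out, to 10 without 6 month control 1715 or 12 month control 9814, 12 without 9756 or 9806, 13 without 1717, 24 without 1713, 28 without 9757 and 137 without 1618. DESeq2 called 442. With the 2 groups fitted alone the count was 6.

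Control GMP differed from control HPC in myeloid and stem cell genes. Both came from control animals with the same identifiers, and the values here are from fits without pairing. The neutrophil elastase gene Elane stood at 11200 ± 5720 CPM in GMP against 29.1 ± 22.9 CPM in HPC at P0 and at 27800 ± 8740 against 247 ± 180 CPM at 10 weeks (SD, n = 4 each). Neutrophil granule genes rose in 19 of 19 at P0 by either adjustment (median 7.45, camera adjusted p = 1.3e-19, and adjusted p = 0.0065 with an estimated correlation) and in 13 of 19 at 10 weeks (14 adjusted over the list alone; median 3.25, 8.7e-10; adjusted p = 0.076 with an estimated correlation). Mecom (-4.55 ± 0.43 and -3.87 ± 0.40) and 14 and 15 of 20 stem and multipotent progenitor genes were lower (15 and 16 adjusted over the list alone; medians -1.90 and -2.74, and adjusted p = 0.011 and 0.0049 with an estimated correlation). MHC class II genes were lower in 9 of 10 at both ages by either adjustment (medians -4.79 and -2.29, 5.3e-24 and 9.1e-07; adjusted p = 0.00012 and 0.076 with an estimated correlation). Lymphoid priming genes were lower in 13 and 15 of 20 (15 at each age adjusted over the list alone; medians -2.50 and -4.22; adjusted p = 0.075 and 0.025 with an estimated correlation), Dntt at 5.95 ± 3.66 against 1490 ± 231 CPM at 10 weeks. In total 1912 genes were higher and 2441 lower at P0, and 2416 and 3025 at 10 weeks (3580 with the 2 groups fitted alone).

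Controls of the same age and population differed between the 2 sets of 10 week libraries. Ppp1r14a, an inhibitor of myosin phosphatase, was lower in the MLL-ENL (x2) set in all 3 populations, at 1.46 ± 0.905 against 14.1 ± 2.47 CPM in HPC (SD, n = 4 each; log2 fold change -3.38 ± 0.36, adjusted p = 0.0039), -3.70 ± 0.31 in pGM and -3.81 ± 0.25 in GMP. HPC had 2 genes higher and 11 lower, pGM 150 and 323, and GMP 157 and 174. Cd74, H2-Aa and H2-Eb1 fell in pGM and GMP (Cd74 by -1.86 ± 0.36 and -2.73 ± 0.40). MHC class II genes had medians of -0.61 and -0.46 (camera adjusted p = 4.1e-05 and 9.8e-05; adjusted p = 0.57 and 0.071 with an estimated correlation; 3 of 10 and 3 of 9 lower, 6 and 3 adjusted over the list alone). Neutrophil granule genes had a median of 1.32 in HPC (5.8e-09; adjusted p = 0.55 with an estimated correlation; 0 of 17 over all genes and 8 higher adjusted over the list alone). These counts hung on single libraries. In HPC the count was 6 without 4892 and 26 without 5899. In pGM it was 1544, 175 and 108 without 76, 80 and 87, and 78, 63, 200 and 152 without 4892, 4894, 5898 and 5899. In GMP it was 840, 1025, 40 and 130 without 76, 80, 87 and 88, and 24, 25, 21 and 40 without 4892, 4894, 5898 and 5899.

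Positions are on GRCm38 with the GENCODE vM21 annotation. Skida1 (ENSMUSG00000054074) spans chromosome 2, 18040676 to 18049051, on the minus strand, Mecom (ENSMUSG00000027684) chromosome 3, 29951296 to 30548008, minus, and Hoxa9 (ENSMUSG00000038227) chromosome 6, 52223100 to 52231089, minus. C1qtnf6 (ENSMUSG00000022440) spans chromosome 15, 78523346 to 78531416, minus, Klhl4 (ENSMUSG00000025597) chromosome X, 114474333 to 114560829, plus, Tifab (ENSMUSG00000049625) chromosome 13, 56173704 to 56178885, minus, and Cd74 (ENSMUSG00000024610) chromosome 18, 60803848 to 60812652, plus. All are protein-coding genes.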

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

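The tests of the 3 patterns weighed here, the test of other splits of the 6 month libraries and the counts of calls shared with other animals were chosen after their results were seen; the other tests of splits were chosen before.

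Libraries labelled 73 at 10 weeks lay far from their groups on the score of up to 50 marker genes of each population. The library labelled 73 HPC scored -1.42, against 2.64 to 3.15 in the other 3 MLL-ENL HPC libraries, and the library labelled 73 pGM 2.89, against -1.87 to -1.45. A mixture of both populations in each sort is argued against: the share of HPC type RNA in the library labelled 73 HPC was 3.2%, inside the -7.8 to 13.1% of the other 7 pGM libraries. An exchange of both libraries stays open as a candidate explanation, since -1.42 lay inside the range of the other 7 pGM libraries (-1.88 to -1.06) and 2.89 inside that of the other 7 HPC libraries (2.37 to 3.45). No biological explanation was tested.

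In P0 HPC, MHC class II, dendritic, monocyte and mast cell genes were lower in MLL-ENL libraries. A smaller share of 1 cell type alone is argued against by the mast cell and basophil list, itself part of the pattern, whose median fell too (-2.06, 6 of 14 members past FDR 0.05, adjusted p = 1.8e-05, but 0.097 and not called with an estimated correlation), and pools of different sex by a median of -2.15 for MHC class II genes among the 2 control and 3 MLL-ENL libraries with transcripts of both sexes (10 of 10 genes lower). A smaller share of dendritic cells in the MLL-ENL sort may account for part of it: of 12 dendritic cell genes outside the MHC class II list and not named for this comparison, 91.7% had a negative log2 fold change (median -2.54, 8 past FDR 0.05), as had 8 of the 8 named in no comparison (median -2.47, 5 past FDR 0.05). In the whole list of 20, of which 8 are also in the fixed lists, 16 fell and 0 rose (edgeR; median -2.63), with Cd74 at 11200 ± 4160 CPM in controls and 1320 ± 612 CPM in MLL-ENL libraries, and Cst3 at 4050 ± 1320 and 711 ± 169 CPM (SD, n = 4 each). A smaller share and lower expression in the same cells (MHC class II median -2.11) cannot be told apart in bulk RNA; the gate used for HPC, and whether it would remove such cells, is not given in the sources used here.

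C1qtnf6 and Klhl4 were lower in MLL-ENL HPC at 10 weeks and were not called at 6 or 12 months. A lower transgene level is argued against at 12 months, where C1qtnf6 had a log2 fold change of -0.18 with a transgene mean of 4.04 CPM, inside the range of 10 week MLL-ENL HPC (2.37 to 6.30 CPM). A sequence variant linked to the transgenes is argued against for Klhl4, at 0.14 ± 0.16 at 6 months and 0.92 ± 0.46 in P0 HPC. A difference between the sets of libraries and fetal against adult induction cannot be told apart (C1qtnf6 difference -2.14 ± 0.34 between 10 weeks and 6 months, not past FDR 0.05 at an adjusted p of 0.066; Klhl4 -4.80 ± 0.68, 0.028), since every adult induction library belongs to 1 set. Age and induction stay open as biological explanations, untested.

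Other libraries lay far from the rest of their group, 12 of 124 groups and measures over 8 measures in all, where chance gives about 1 in 20 groups. Total counts were 21.1 M in the MLL-ENL (x2) set control GMP 4894 (others 17.7 to 17.8), and the marker score was -1.53 in control pGM 4894 of that set (others -1.37 to -1.36). The markers were chosen from the controls of that same set. C1qtnf6 stood at 5.51 CPM in 10 week MLL-ENL pGM 78 (others 3.05 to 3.45) and 49.4 CPM in 12 month control HPC 9814 (others 31.5 to 32.4). Klhl4 stood at 0 CPM in P0 control GMP 4 (others 0.0796 to 0.0903), 0.415 CPM in P0 MLL-ENL GMP 4 (others 0.184 to 0.212), 1.72 CPM in 10 week MLL-ENL HPC 74 (others 0 to 0.247) and 0.25 CPM in 10 week MLL-ENL GMP 74 (others 0). The Klhl4 values in GMP rest on few reads near the floor, where the rate of 1 in 20 need not hold. Sva stood at 2.67 CPM in 10 week MLL-ENL GMP 78 (others 1.17 to 1.23) and Hoxa9 at 24.1 CPM in control pGM 5899 of the MLL-ENL (x2) set (others 27.2 to 27.8).

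Effects differed between groups, by a test of the difference itself, for 238 genes in HPC, 1 in pGM and 1 in GMP between P0 and 10 weeks. Between MLL-ENL (x2) and MLL-ENL they differed for 2 genes in pGM and 1 in GMP, and between 10 weeks and 6 months for 1 gene in HPC. Splits of the libraries were tested in fits of the compared groups alone. For P0 against 10 weeks in HPC, 6 of 100 splits gave at least the real 133 genes (highest other 1185). In pGM 8 of 100 gave the real 2 (highest other 45), and in GMP 13 of 100 the real 1 (highest other 31). Chance is not excluded for these 3. For MLL-ENL (x2) against MLL-ENL in pGM, 2 of 100 gave at least the real 2. This share was not adjusted for the number of comparisons tested, so it does not exclude chance. The 1 other split gave 6 genes, more than the real count, and the count was 1 without any of 6 libraries. In GMP 7 of 100 gave the real 1 (highest other 26), and chance is not excluded. In HPC 100 of 100 gave the real 0 by edgeR (highest other 148), and DESeq2 called 9. By edgeR 330 of 13601 genes had an unadjusted p under 0.05, fewer than chance alone gives at that threshold. Between 10 weeks and 6 months 20 of 100 gave the real 1 (highest other 219), and chance is not excluded. Between 6 and 12 months 100 of 100 gave the real 0 by edgeR (highest other 62), and DESeq2 called 1. By edgeR 333 of 13059 genes had an unadjusted p under 0.05, again fewer than chance alone gives. These tests shuffled genotype within each pair of groups, so a split can keep the real genotypes of 1 pair. Splits with 1185, 219, 148, 62, 45, 31, 26 and 6 genes may therefore hold the genotype effect of that pair or a structure of the samples. What they part was not tested, so these shares cannot decide on chance.

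By counts of genes, here and for controls, the real grouping is set against the other splits. Where no other split gave as many, the share of 1 of 35 is the smallest possible. Shares were not adjusted for the number of comparisons, so such a share argues against chance without excluding it. For MLL-ENL against control no other split gave as many in P0 HPC (1 of 35 splits, real 1578, highest other 0) and P0 pGM (1 of 35, real 40, highest other 0). Another split gave as many in P0 GMP (2 of 35, real 10, highest other 26). Of the 8 splits there that part all 4 pairs of replicate numbers, none besides the real one called a gene, and the 26 came from splits that part fewer. At 10 weeks chance is not excluded in HPC (3 of 35, real 7, highest other 12), pGM (2 of 35, real 5, highest other 10) or GMP (4 of 35, real 2, highest other 1639). It is not excluded at 6 months (9 of 35, real 1, highest other 56). At 12 months 35 of 35 gave the real 0 by edgeR (highest other 18), while DESeq2 called 15 and 882 genes had an unadjusted p under 0.05 in the fit of both ages. For MLL-ENL (x2) chance is not excluded in HPC (2 of 35, real 74, highest other 652). No other split gave as many in pGM (1 of 35, real 111, highest other 28) and GMP (1 of 35, real 44, highest other 14).

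The calls themselves say more than their number in the 6 comparisons with at least 1 gene where another split gave as many. Of the 7 genes in 10 week HPC, 6 were called in the same direction in MLL-ENL (x2) HPC, from other animals, and no other of the 35 splits shared any (highest other 0). Of the 5 in 10 week pGM, 4 were shared with MLL-ENL (x2) pGM, and of the 10 in P0 GMP, 6 with MLL-ENL (x2) GMP (highest other 0 for both). MLL-ENL (x2) HPC shared 15 of its 74 genes with 10 week HPC (highest other 0). The shared calls argue against chance without excluding it, and leave chance open for the rest of each count. These shares are 1 of 35, the smallest possible, and the test was chosen after its results were seen. The splits kept every library in its labelled group. Cd14, shared in 10 week HPC and pGM, lost its call in both without the libraries labelled 73, with folds close to those before. With P0 HPC, MLL-ENL (x2) HPC shared 37 genes, but another split shared 28, so that number is not used against chance. At 6 months the 1 gene was Sva, shared with 12 months (highest other 0; other splits shared up to 5 genes with P0 HPC) and at no less than 1.04 CPM in MLL-ENL libraries and no more than 0.179 CPM in controls over the whole series, which excludes chance for it. In 10 week GMP 3 of 35 splits shared at least the real 2 genes with MLL-ENL (x2) GMP (highest other 7), and chance is not excluded for that count. It is excluded for C1qtnf6 there, at -2.86 ± 0.28 with no overlap of the libraries, since it fell in P0 GMP (-1.76 ± 0.27) and MLL-ENL (x2) GMP (-5.41 ± 0.37) of other animals too, and for Sva by the levels above.

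The splits with 1639, 652, 56 and 18 genes point to a structure of the samples, looked at after the data were seen. The highest other splits in 10 week HPC (12) and pGM (10) part libraries with Xist from those with Y transcripts, with 2 of each genotype on each side, and in 10 week GMP that split gave 140 genes. The split with 56 genes at 6 months parts the libraries with Xist from the rest, and the one with 18 at 12 months those with Y transcripts, 3 controls and 1 MLL-ENL library, from the rest. The splits with 1639 and 652 genes do not follow sex. The one with 652 sets controls 4892 and 4894 and MLL-ENL (x2) 5293 against the other 4, as does the one with 28 in pGM, and its cause was not tested.

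Among controls no other split gave as many genes for P0 liver against 10 week bone marrow, age and tissue together. This held in HPC (1 of 35, real 1929, highest other 0), pGM (1 of 35, real 1307, highest other 1) and GMP (1 of 35, real 1054, highest other 12). The same held for GMP against HPC at P0 (1 of 35, real 4204, highest other 1) and 10 weeks (1 of 35, real 3580, highest other 5). Chance is not excluded for 12 against 6 months (3 of 35, real 6, highest other 85). Between the sets of 10 week controls no other split gave as many in pGM (1 of 35, real 473, highest other 6) and GMP (1 of 35, real 331, highest other 13). In HPC other splits did (3 of 35, real 13, highest other 667). The splits with 85 and 667 genes point to a structure of the samples, and neither parts the libraries by sex.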

How the results depend on the processing

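Counts of genes past FDR 0.05 moved in these settings, and the cause was not tested. With DESeq2 in place of edgeR, P0 pGM went from 52 to 103 and P0 GMP from 17 to 39. At 10 weeks HPC went from 26 to 59, pGM from 14 to 40 and GMP from 3 to 10. For MLL-ENL (x2) HPC went from 142 to 275, pGM from 119 to 256 and GMP from 128 to 214. At 6 months 1 became 4, and at 12 months 1 became 15. For P0 against 10 weeks DESeq2 gave 375 in HPC (edgeR 238), 15 in pGM (edgeR 1) and 7 in GMP (edgeR 1). For MLL-ENL (x2) against MLL-ENL it gave 9 in HPC (edgeR 0), 25 in pGM (edgeR 2) and 7 in GMP (edgeR 1). It gave 1 for 6 against 12 months (edgeR 0) and 12 for 10 weeks against 6 months (edgeR 1). Controls at 12 against 6 months went from 73 to 442. Between sets of controls DESeq2 gave 59 in HPC (edgeR 13), 1280 in pGM (edgeR 473) and 1316 in GMP (edgeR 331).

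With only the compared groups in the fit, P0 GMP went to 10, 10 week HPC to 7 and 10 week pGM to 5. MLL-ENL (x2) HPC went to 74 and GMP to 44, and 12 months to 0. P0 against 10 weeks went to 133 in HPC and 2 in pGM. Controls went to 1054 for P0 against 10 weeks in GMP, 6 for 12 against 6 months and 3580 for GMP against HPC at 10 weeks. With the replicate number as a block P0 HPC went to 2551, P0 pGM to 158 and P0 GMP to 157. Without a filter on low counts 10 week HPC went to 42, and controls to 13 for 12 against 6 months and 52 for the sets in HPC. MLL-ENL (x2) against MLL-ENL went to 13 in pGM and 11 in GMP, and 10 weeks against 6 months to 5. With all 84 libraries in 1 fit, MLL-ENL (x2) against MLL-ENL went to 6 in pGM and 13 in GMP, and 10 weeks against 6 months to 9. The sets of controls went to 111 in HPC and 1276 in GMP. With the controls of both sets pooled, MLL-ENL (x2) pGM went to 267. With RLE factors P0 against 10 weeks in pGM went to 2. Without both libraries labelled 73, chosen after seeing the data, P0 pGM went to 87 and 10 week pGM to 7. P0 against 10 weeks went to 153 in HPC, 2 in pGM and 2 in GMP, and 10 weeks against 6 months to 3. Of 191 list results called with the preset correlation, 33 were called with the estimated one.

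Median log2 fold changes of lists changed sign in 10 cases. With the replicate block, neutrophil granule genes in P0 GMP were at -0.01, called there (adjusted p = 0.012) and not without the block. The block also ended the calls in P0 pGM of lymphoid priming, at -0.24 (0.071), and erythroid genes, at 0.14 (0.88). It called further lists in P0 HPC, pGM and GMP and in control GMP against HPC at 10 weeks that were not called without it. Without both libraries labelled 73, monocyte and dendritic genes were at -0.20 in 10 week HPC and -0.26 for 10 weeks against 6 months. Without the library labelled 73 HPC alone they were at -0.20 and -0.26 as well. Without P0 control pGM 3, lymphoid priming genes were at 0.12 in P0 pGM and 0.86 for P0 against 10 weeks in pGM. Without 10 week control pGM 88, neutrophil granule genes were at 0.34 in pGM. Without 12 month control 9756 they were at 0.92 at 12 months and at -0.87 in controls at 12 against 6 months.

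For these lists the other end of the medians with 1 library left out was -1.33 for lymphoid priming in P0 pGM and -0.54 for P0 against 10 weeks, without P0 control pGM 2. It was 0.96 for monocyte and dendritic genes in 10 week HPC and 1.04 for 10 weeks against 6 months, without the MLL-ENL library 78. It was -0.44 for neutrophil granule genes in 10 week pGM without control 76, -1.39 at 12 months without MLL-ENL 9431, and 0.72 in controls at 12 against 6 months without 1717.

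Leaving out 1 library in turn gave these lowest and highest counts. For MLL-ENL against control they were 604 and 855 in P0 HPC (1133 with all libraries), 22 and 49 in P0 pGM, and 11 and 22 in P0 GMP. At 10 weeks they were 17 and 32 in HPC, 6 and 15 in pGM, and 3 and 4 in GMP. MLL-ENL (x2) gave 74 and 167 in HPC, 75 and 112 in pGM, and 67 and 124 in GMP. At 6 and at 12 months all gave 1. P0 against 10 weeks gave 116 and 328 in HPC, 1 and 2 in pGM, and 1 throughout in GMP. MLL-ENL (x2) against MLL-ENL gave 0 and 1 in HPC, 1 and 3 in pGM, and 1 and 2 in GMP. It was 0 throughout for 6 against 12 months by edgeR and 0 to 3 for 10 weeks against 6 months. Controls at P0 against 10 weeks gave 1858 and 2232 in HPC, 765 and 1357 in pGM, and 1145 and 1925 in GMP, and 10 and 137 for 12 against 6 months. GMP against HPC gave 3674 and 4217 at P0 and 4372 and 5669 at 10 weeks. Sets of controls gave 6 and 26 in HPC, 63 and 1544 in pGM, and 21 and 1025 in GMP. Lists called were 182 to 198, and named genes called 789 to 822 of 867.

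Of the 822 named genes called, 6 lost their call with DESeq2 (811 kept it), 11 with RLE factors (811 kept it) and 38 without a filter on low counts (784 kept it). With only the compared groups in the fit 116 lost it and 603 kept it, with all 84 libraries in 1 fit 17 and 67, and with the controls of both sets pooled 14 and 116. Without both libraries labelled 73, 31 lost it and 583 kept it, and with the replicate block 1 and 303. Overlapping calls rose from 341 to 461 at FDR 0.10.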

Other observations

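Values here were chosen after they were seen. Sva was called higher in all 11 comparisons of genotypes, at 4.72 ± 0.971 CPM in P0 MLL-ENL pGM and 4.8 ± 1.02 CPM in GMP (SD, n = 4 each). It stood at 2.21 ± 0.288 CPM in MLL-ENL (x2) HPC at 10 weeks (SD, n = 3). In controls it was at most 0.179 CPM, with 36 libraries at 0. No source for these reads was tested.

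Without the libraries labelled 73, P0 HPC and 10 week HPC shared 11 genes up and 2 down, with 1 opposite. The log2 fold changes had r = 0.07 over genes, which are not independent replicates, beside -0.06 with all libraries.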
